A study of Saccharomyces cerevisiae with 35 samples.

How the data were processed

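The series holds 35 SLAM-seq libraries of Saccharomyces cerevisiae. Per the labels, cells grew in SDC medium at 30 °C, Crm1(T539C) cells (mutant Crm1 below) were given 185 nM leptomycin B (LMB) for 30 min, and Nup1-AID or Nup2-AID cells were given 3-IAA, with ethanol as the control. By the protocol, which is the same for every library, cultures then got 0.2 mM 4-thiouracil for 6 min, and their RNA was alkylated for 15 min in 10 mM iodoacetamide before QuantSeq 3′ mRNA libraries were made. The protocol gives 500 µM 3-IAA for 16 h, while 14 Nup1-AID libraries are labelled 1 h and labels of single libraries give doses from 500 to 506 µM. Groups were formed from the labels of each library, which gave 3 LMB and 3 ethanol libraries of mutant Crm1, 3 and 3 of Nup2-AID at 16 h, 7 and 7 of Nup1-AID at 1 h, and 4 3-IAA and 5 ethanol libraries of Nup1-AID at 16 h. Whether a replicate number joins a treated and a control library is not given in the sources used here. Read lengths, trimming and mapping settings are not given there either.

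The authors counted reads with slamdunk 0.4.2 against the sacCer3 build, and they list DESeq2 1.46.0. Per the file headers, each deposited table gives all reads and reads with at least 1 T-to-C conversion as raw counts for 6681 windows. The deposited tables also give the coverage of T positions and the conversions on them as signal, and CPM computed by the authors' tool. The counts of reads were used for all tests, the signal for conversions per covered T, and the deposited CPM only to work out mapped reads. CPM is printed on 2 scales. Group means of tested genes were computed again from counts and TMM factors, as was the mean of the Yap1 list in each library. Other CPM of single libraries, sums of marker genes with their group means, and group means of FUR1 and FUR4 are counts over window reads without TMM factors. No table held a read mapped to several places, so alternatives about such reads had nothing to change and were not run. Windows held 68.05% to 70.63% of mapped reads with LMB, 75.23% to 77.83% in its controls and 71.43% to 95.04% in the AID strains, and the most counted gene held 0.945% to 5.54% of a library's window reads. Depth was 2.10 to 20.96 M window reads per library.

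Windows are 825 bp long and mostly end 325 bp past the 3′ end of their gene. Of 6681 windows 6007 were matched to a RefSeq gene by systematic name and 674 were not, and among those matched 172 lie more than 5 bp from the usual place, 169 of them on the plus strand. They include 52 of the 137 ribosomal protein genes. Another 1094 windows overlap a window of the same strand. Window starts may differ by 1 base, since the coordinate base of the tables is not given in the sources used here. Labels were checked against CRM1, NUP1, NUP2, URA3 and LEU2, and against sums of 4 alpha-cell genes, 6 a-cell genes, 7 meiotic genes and 8 post-diauxic genes.

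Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM factors within the read class, and the quasi-likelihood F-test with Benjamini-Hochberg adjustment at 0.05. mutant Crm1 and Nup2-AID were fitted on their own 6 libraries and Nup1-AID on its 23 libraries with a shared dispersion. Differences between treatment effects used the 23 Nup1-AID libraries or the 15 libraries at 16 h. The converted share of a gene's reads was tested as the interaction of treatment and conversion state with library as a term, for genes with a mean of at least 10 unconverted reads, a limit set after the data were seen. Its log2 values are odds ratios of converted to unconverted reads. The share of converted reads per library was compared by two-sided exact permutation tests, whose smallest p is 0.1 for 3 against 3 libraries, 0.000583 for 7 against 7 and 0.00794 for 4 against 5. Biological coefficients of variation in total reads were 0.113 for mutant Crm1, 0.361 for Nup2-AID and 0.594 for Nup1-AID, and the lowest chi-square per degree of freedom between 2 libraries of a group was 4.47. Library shares have Wilson 95% intervals, and these and the floors (3 counts over a group, for genes at 0 throughout it) cover counting error only, since reads carry no molecular barcodes.

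Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, and adjusted over 28 lists. Of these 1 is not reported here but stays in the adjustment and in the numbers of lists called. The others were Gcn4 targets and amino acid biosynthesis, methionine and sulfur assimilation, Yap1 targets, Pdr1 and Pdr3 targets, Hsf1 targets and chaperones, general stress genes (Msn2 and Msn4), ribosomal proteins, ribosome biogenesis, the nuclear pore complex, karyopherins and transport factors, genes reported at the nuclear pore, and inositol and phospholipid genes (Ino2 and Ino4). They were also phosphate starvation genes (Pho4), the iron regulon (Aft1), the zinc regulon (Zap1), mating pheromone response, G1/S genes (SBF and MBF), core histones, G2/M genes (CLB2 cluster), proteasome genes (Rpn4), glycolysis and fermentation, respiration and glucose-repressed genes, sterol biosynthesis, cell wall integrity genes (Rlm1), adenine genes (Bas1 and Pho2), polyadenylation, mRNA decay and export factors, and chromosome ends (within 20 kb). Groups, tests, lists, markers and the rule for naming genes were fixed before the data were examined. That rule took genes with adjusted p under 0.05, a mean of at least 20 reads and every treated library on the same side of the control mean. It kept the 8 highest and 8 lowest fold changes in total reads, the 4 highest and 4 lowest in nascent reads, and the 3 smallest p-values per direction in other tests. It added the 3 members with the smallest p of each list past camera, the 3 smallest p-values where nothing passed, and CRM1, NUP1, NUP2, URA3 and LEU2 always. The text names a part of these.

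Pairing by replicate number was checked as the correlation of a treated library's deviation with that of the control of the same number. It was 0.307 to 0.788 for Nup1-AID at 1 h, where 4 of 7 libraries matched their own number best, and −0.548 to 0.184 elsewhere. Alternatives were DESeq2 1.42.0, RLE scaling, other count filters (none, or a mean of at least 50 reads), blocks by replicate number or adjacent library number, fits of only 2 groups, total-read scaling of converted reads, quasi-binomial tests, sign-flip tests, conversions per covered T, shares without the 20 most counted genes, and each library left out in turn. Blocks by adjacent library number kept only libraries with an adjacent partner. They left out Nup2-AID 3-IAA replicate 1 and ethanol replicate 3, and Nup1-AID 16 h ethanol replicate 1. Blocks by replicate number in Nup1-AID were fits of 2 groups, and at 16 h they left out ethanol replicate 5. Subsets of Nup1-AID libraries, list tests with a replicate block, that block with 1 replicate number left out, converted reads less a background share, overlaps of calls with the Nup2-AID libraries or block changed, and fits without misplaced or overlapping windows were chosen after seeing the data. In a self-test with planted changes the tests recovered 90% of 2-fold and 100% of 4-fold changes in LMB total reads and 64% and 93.8% in its converted reads. For Nup2-AID they recovered 4% and 70.7%, and 16% and 67%. For Nup1-AID at 1 h they recovered 14% and 70.7%, and 0% and 42.1%, and at 16 h 8% and 54.1%, and 0% and 0%. Difference tests recovered at most 30% of 4-fold changes. The test of converted shares recovered 78% and 100% for LMB, 22% and 93.8% for Nup2-AID and 0% for Nup1-AID. Its self-test gave treated libraries the mean labelling of their controls and a preset spread, not one taken from the data. It may thus overstate recovery at the lower label of LMB and of Nup2-AID with 3-IAA. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for library measures and figures.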

Results

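RNA was measured by SLAM-seq in 35 libraries of budding yeast (Saccharomyces cerevisiae) to see how nuclear transport factors affect new and total mRNA. Cells were given 4-thiouracil for 6 min before harvest, and iodoacetamide then makes each built-in thiouracil read as a T-to-C change. Reads that carry at least 1 such change are called converted or nascent here, and all reads together are called total. In the Crm1 strain the point mutation T539C in the exportin Crm1 lets leptomycin B (LMB) block it, and 3 libraries with 185 nM LMB for 30 min stand against 3 with the solvent ethanol. In the Nup2-AID strain a degron lets the auxin 3-IAA trigger the loss of Nup2, a protein of the nuclear basket of the pore, and 3 libraries with 3-IAA for 16 h stand against 3 with ethanol. In the Nup1-AID strain, with a degron on the basket protein Nup1, 7 libraries with 3-IAA stand against 7 with ethanol at 1 h, and 4 against 5 at 16 h. Reads within gene windows (M, 1e6 reads) ranged from 4.63 to 6.78 M per library with LMB and from 5.53 to 6.11 M in its controls. For Nup2-AID they ranged from 2.10 to 6.10 M with 3-IAA and from 4.50 to 20.96 M with ethanol. For Nup1-AID at 1 h the ranges were 2.63 to 9.97 M with 3-IAA and 3.54 to 11.8 M with ethanol, and at 16 h they were 3.93 to 9.15 M and 5.68 to 8.11 M. Whether replicates came from separate cultures is not given in the sources used here. P-values of tests between libraries thus measure the spread between these libraries only. Fisher's exact test of overlaps takes genes as its units, and camera sets the genes of a list against the other genes. Errors after a log2 fold change are SE of the edgeR fit, and those after counts per M (CPM) or percentages are SD.

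The share of converted reads asks how much RNA was labelled during the pulse. It was 4.66% ± 0.450 (SD, n = 3) with LMB and 20.2% ± 1.24 (n = 3) in its controls, a difference of −15.5 percentage points. It was 2.04% ± 0.736 (n = 3) in Nup2-AID with 3-IAA and 37.4% ± 6.67 (n = 3) with ethanol, a difference of −35.3 points. In each of these comparisons the two-sided exact permutation p was 0.1, the smallest that 3 libraries against 3 allow. Nup1-AID libraries differed from each other far more than their groups did. At 1 h the share was 12.6% ± 15.3 (n = 7) with 3-IAA and 14.6% ± 19.04 (n = 7) with ethanol (exact permutation p = 0.826), and at 16 h it was 15.4% ± 15.3 (n = 4) and 15.5% ± 14.7 (n = 5) (exact permutation p = 0.960). The 1 h difference of −1.98 points turned positive without ethanol replicate 1 (1.67) or 6 (2.93) and without 3-IAA replicate 3 (0.02), 4 (0.06) or 5 (0.06). The 16 h difference of −0.196 points turned positive without ethanol replicate 1 (3.79), 2 (2.97) or 3 (0.177) and without 3-IAA replicate 1 (4.37) or 2 (4.02). The change at 16 h differed between Nup1-AID and Nup2-AID by 35.1 points (exact permutation p = 0.0184 over 1960 rearrangements of the strain within each treatment). That test takes the strains as alike in both treatments, so its p can also come from a difference in baseline. With ethanol the strains already lay at 15.5% and 37.4%. Library names put each strain in a batch of its own, so strain and batch coincide in the 35.1 points. Replicates 2 to 5 of both 1 h groups and ethanol replicates 4 and 5 at 16 h had 0.346% to 0.810% converted reads, and 3-IAA replicates 1 and 2 at 16 h had 1.64% and 2.69%. Whether those 10 libraries under 1% were given 4-thiouracil and iodoacetamide like the others is not given library by library in the sources used here, so the Nup1-AID shares, converted reads and converted shares of genes rest in part on libraries with hardly any label. The Wilson 95% interval of a library's share reached at most 0.0459 points to either side, and such intervals cover counting error only.

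**Figure D1:**
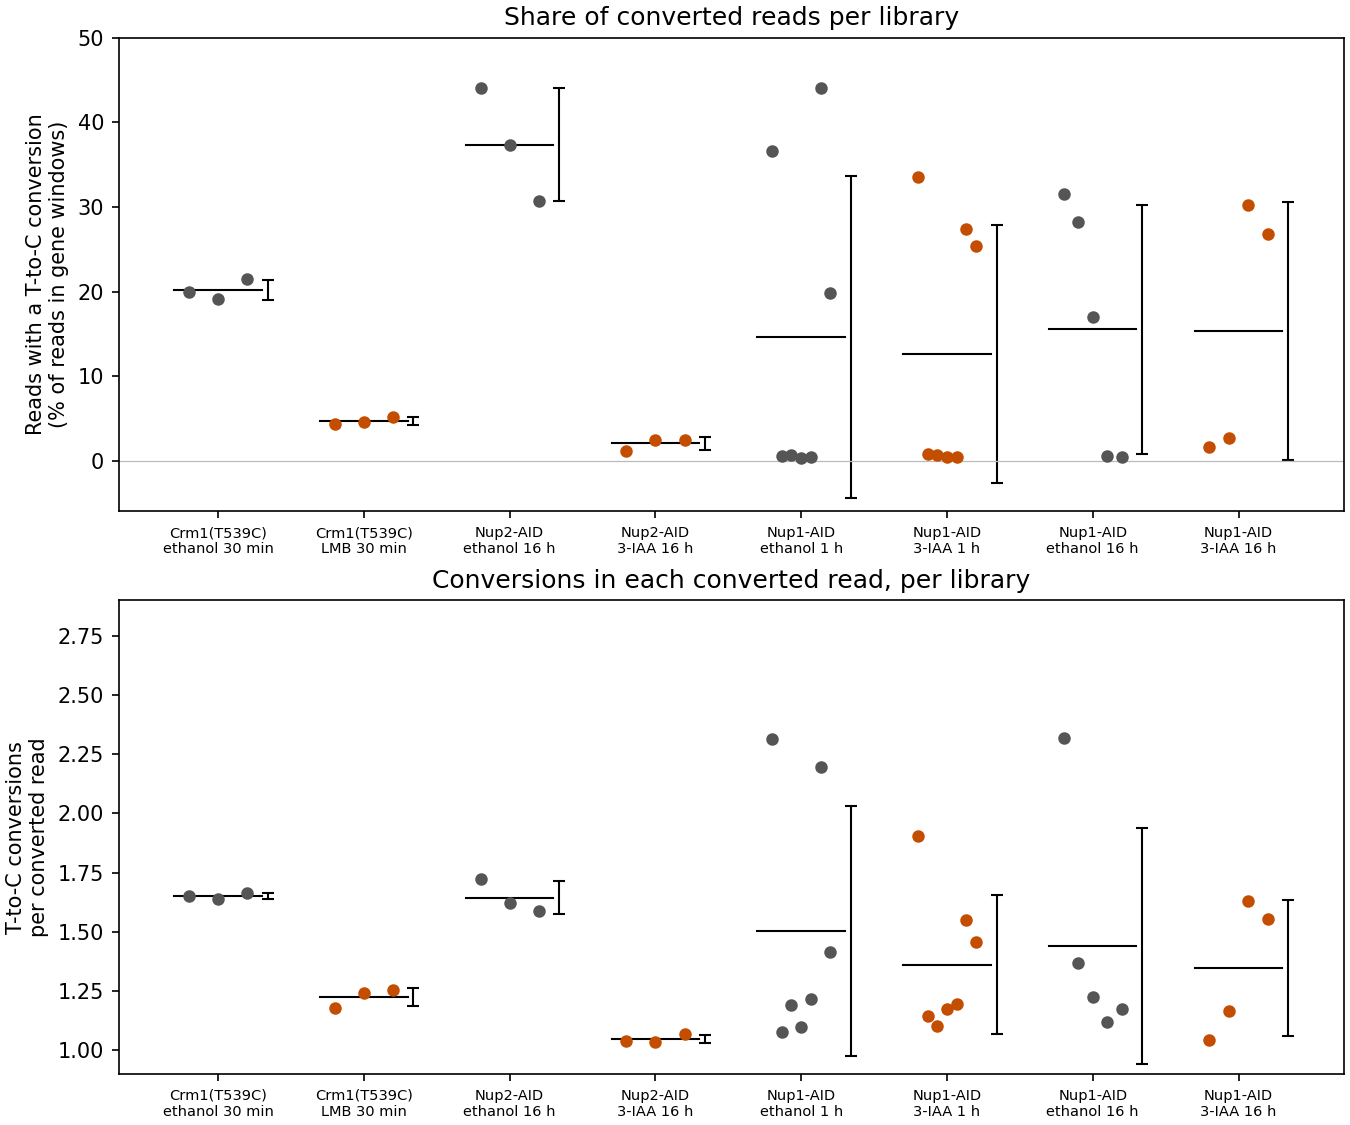
Share of reads with a T-to-C conversion (% of reads in gene windows, upper panel) and T-to-C conversions per converted read (lower panel), with 1 point per library, horizontal lines at group means and bars of 1 SD. The LMB libraries lie between 4.29% and 5.16% and their controls between 19.1% and 21.5%, while the Nup1-AID groups each hold libraries below 3% and above 25%.

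The first comparison asks which transcripts change in amount when Crm1, the exportin of proteins with a leucine-rich export signal, is blocked. After LMB, transcripts of ribosomal proteins fell together. RPS3 (YNL178W, chromosome XIV, window 302902 to 303727 in sacCer3), which codes for a protein of the small subunit, fell 5.73-fold, from 3145 ± 205 to 548.8 ± 24.2 CPM (log2 −2.52 ± 0.11, n = 3 and 3, edgeR adjusted p = 3.74e-10). RPL8A (YHL033C, chromosome VIII, 34930 to 35755), of the large subunit, fell 11.1-fold, from 275.1 ± 62.1 to 24.8 ± 0.574 CPM (adjusted p = 5.15e-10). RPL33B (−3.42 ± 0.26), RPL16A (−2.99 ± 0.16), RPS16B (−2.44 ± 0.10) and RPS7B (−2.43 ± 0.10) fell too. Of the 131 ribosomal protein genes tested, 99 fell, 7 rose and 25 were not called, with a median log2 change of −1.56. The list passed camera (adjusted p = 2.35e-46) and held its call with an estimated correlation (adjusted p = 0.0245). Counting windows of 46 of these genes lie away from the gene's 3′ end. Among the other 85 genes 84 fell and the median was −1.94, whereas in those 46 genes 15 fell, 7 rose and the median was −0.21.

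**Figure D2:**
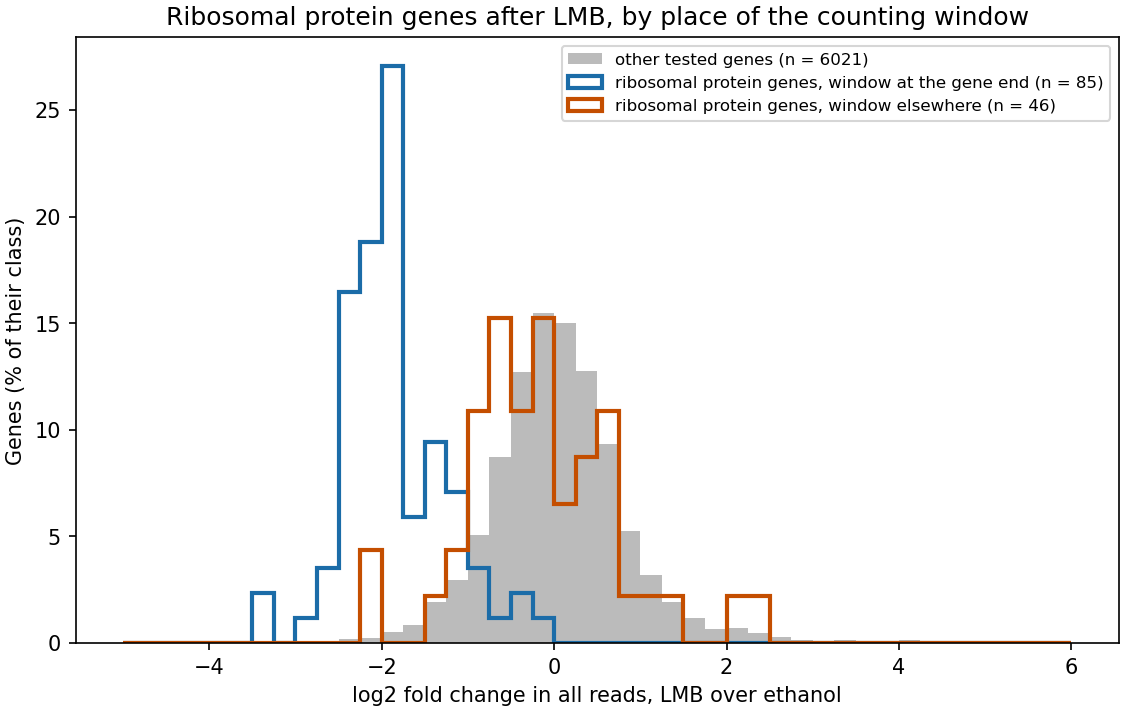
Distribution of log2 fold changes (LMB over ethanol, all reads) as % of the genes of each class, for other tested genes and for ribosomal protein genes with the counting window at the gene end or elsewhere. The 85 genes with a window at the gene end have a median of −1.94 and the 46 others a median of −0.21.

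Genes of amino acid synthesis and chaperone genes also fell after LMB. ARG1 (argininosuccinate synthetase) fell 4.77-fold (log2 −2.25 ± 0.10, from 1134 ± 54.1 to 237.9 ± 1.89 CPM, adjusted p = 4.23e-10), and ARG4 of the same pathway fell by 1.80 ± 0.10 on the log2 scale. Of the 53 targets of Gcn4, the activator of amino acid synthesis genes, 42 fell and 4 rose (median −0.91, camera adjusted p = 2.36e-12). This list also held its call with an estimated correlation (adjusted p = 0.0245). HSP42 (small heat shock protein, −2.01 ± 0.12), SSA4 (inducible Hsp70, −2.97 ± 0.14) and HSP78 (mitochondrial disaggregase, −2.46 ± 0.14) fell among the targets of heat shock factor Hsf1. Of those 27 genes 23 fell and 4 were not called (median −0.98, adjusted p = 7.54e-13), with an adjusted p of 0.125 with an estimated correlation. GPD1, which codes for the glycerol-3-phosphate dehydrogenase of osmotic stress, fell by 2.88 ± 0.11. Of 31 general stress genes 27 fell and 1 rose, among them SPI1 (−2.36 ± 0.12), HXK1 (−1.34 ± 0.11) and GRE3 (−1.13 ± 0.10), with a list median of −0.69 and adjusted p = 0.226 with an estimated correlation.

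Oxidative stress genes rose after LMB. FLR1, which codes for a multidrug transporter, rose 4.49-fold (log2 2.17 ± 0.11, from 418.9 ± 19.4 to 1879 ± 176 CPM, adjusted p = 1.08e-09), and so did ATR1 (2.27 ± 0.10), another transporter, and AAD4 (2.22 ± 0.10), a putative aryl-alcohol dehydrogenase. Of 28 targets of Yap1, the oxidative stress activator, 20 rose and 3 fell (median 0.84, camera adjusted p = 1.38e-09), with adjusted p = 0.125 with an estimated correlation. YKL070W (chromosome XI, 306220 to 307045), an uncharacterised gene, rose 23.9-fold, from 13.4 ± 0.749 to 319.7 ± 16.6 CPM (adjusted p = 2.36e-12), and the uncharacterised YER148W-A and YHR145C rose by 4.46 ± 0.36 and 4.21 ± 0.27 on the log2 scale. Genes of ribosome assembly rose, with UTP9 (1.37 ± 0.12), UTP21 (1.19 ± 0.11) and SOF1 (1.11 ± 0.10) of the small subunit processome among them. Of those 67 genes 46 rose and 21 were not called (median 0.45), and adjusted p was 0.125 with an estimated correlation. Proteasome genes rose in 21 of 35 cases and fell in 1 (median 0.36), and their list had adjusted p = 0.331 with an estimated correlation. Among them were RPN4 (1.55 ± 0.12), the activator of the group, UFD1 (1.03 ± 0.11) and RPT2 (0.87 ± 0.09).

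After LMB, in glycolysis and fermentation, 18 of 21 genes fell and 1 rose (median −0.91), with PGI1 (−1.24 ± 0.11), PDC1 (−1.28 ± 0.11) and the glucose transporter HXT4 (−1.58 ± 0.13). Respiratory and glucose-repressed genes fell in 40 of 53 cases (median −0.58), as with COX6 (−1.77 ± 0.11) and ACO1 (−1.38 ± 0.11). Both of these lists had adjusted p = 0.249 with an estimated correlation. Adenine and glycine cleavage genes under Bas1 fell in 13 of 14 cases (median −0.79), with GCV2 (−1.92 ± 0.12) and ADE1 (−0.93 ± 0.09), and adjusted p = 0.0729 with an estimated correlation. Cell wall genes fell in 14 of 19 cases (median −0.63), as CWP1 (−1.37 ± 0.10) and PIR3 (−1.40 ± 0.10) show. Methionine and sulfur genes fell in 15 of 24 cases (median −0.53), with MET14 (−1.60 ± 0.13) and SAM2 (−1.09 ± 0.09). For inositol and phospholipid genes 9 of 13 fell and 2 rose (median −0.47), including INO1 (−1.85 ± 0.12) and OPI3 (−1.17 ± 0.10), and for genes reported at the nuclear pore 6 of 12 fell and 2 rose (median −0.37), including HIS4 (−1.99 ± 0.16). Each of these last 4 lists had adjusted p = 0.226 with an estimated correlation. Mating genes fell in 11 of 20 cases and rose in 4 (median −0.47, adjusted p = 0.249 with an estimated correlation), with FUS1 (−1.53 ± 0.11) and AGA1 (−1.81 ± 0.12). These libraries, labelled MATalpha, held 114 to 148 CPM from genes of alpha cells. Genes of a cells held 1669 to 1939 CPM with LMB and 2941 to 3501 CPM in the controls. The markers of mating type thus go against the label, and the sources used here do not settle which is right. Meiotic genes held 276 to 358 CPM with LMB against 48.6 to 53.7 CPM without.

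In all, 1763 of 6152 genes rose and 1724 fell in total reads (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 534 and 479 of them by over 2-fold, and 15 of the 28 lists passed camera. These values are scaled by TMM factors, which put the median gene at a log2 change of 0.01. The near balance of rises and falls is therefore relative to that scale. Gene windows held 68.05% to 70.63% of mapped reads with LMB and 75.23% to 77.83% in the controls. Adjusted over the list alone, 101 ribosomal protein genes fell, 19 glycolytic genes fell, 47 ribosome assembly genes rose and 2 fell, 15 methionine genes fell and 1 rose, 5 mating genes rose and 11 fell, and the counts of the other called lists above were the same. CRM1 itself, carried on a plasmid, had a log2 change of 0.38 ± 0.18 (adjusted p = 0.0871), which was 0.48 with adjusted p = 0.0450 without ethanol replicate 3. LEU2, the marker that replaces the chromosomal CRM1, had 0.44 ± 0.23 (adjusted p = 0.118), which was 0.67 with adjusted p = 0.0131 without LMB replicate 3. NUP1 (−0.04 ± 0.10) and NUP2 (−0.05 ± 0.10) were not called, and URA3 fell by 1.01 ± 0.10.

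Converted reads ask which of these genes also changed in newly made RNA. Part of them can be background, reads of unlabelled RNA with a chance T-to-C change. Taken at the share of the least labelled 5% of the 500 most counted genes, background is 34.2% to 36.7% of converted reads with LMB and 15.0% to 16.4% in the controls. Taken at 0.810% of reads, the highest share in a Nup1-AID library with hardly any label, it is 15.7% to 18.9% and 3.76% to 4.24%. Values are scaled by TMM factors within converted reads, so they are relative to the converted reads of other genes. Scaled by total reads instead, the median gene had a log2 change of −2.30, and genes that flip sign on that scale are given with that value. Chaperone RNA fell in this fraction too: SIS1 (Hsp40, −2.33 ± 0.15, from 2505 ± 669 to 496.2 ± 58.1 CPM, n = 3 and 3, adjusted p = 1.36e-18), HSP42 (−1.93 ± 0.12) and BTN2 (−1.84 ± 0.11). Of 27 Hsf1 targets 23 fell (median −1.10, camera adjusted p = 1.93e-37), with adjusted p = 0.0947 with an estimated correlation. Adenine genes fell in 13 of 14 cases (median −1.40, adjusted p = 0.195 with an estimated correlation), with GCV2 (−2.79 ± 0.36) and ADE17 (−1.96 ± 0.19). Methionine genes fell in 15 of 24 cases (median −0.78), with MET17 (−1.67 ± 0.13), and Gcn4 targets fell in 27 of 53 and rose in 3 (median −0.70), with ARG1 (−1.46 ± 0.15) falling and LYS20 rising (1.56 ± 0.12, and −0.76 scaled by total reads). Both of those lists had adjusted p = 0.0947 with an estimated correlation. Mating genes fell in 9 of 18 cases and rose in 2 (median −0.72, adjusted p = 0.122 with an estimated correlation), with AGA1 (−3.26 ± 0.25) and FUS1 (−2.22 ± 0.24). Ribosomal protein RNA fell in 40 of 108 cases and rose in 15 (median −0.34), with adjusted p = 0.172 with an estimated correlation. Genes reported at the nuclear pore fell in 3 of 9 cases and rose in 1 (median −0.50, adjusted p = 0.195 with an estimated correlation), HIS4 among them (−1.96 ± 0.29).

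Among converted reads that rose after LMB, YKL070W rose 71.7-fold (log2 6.16 ± 0.23, from 9.555 ± 3.12 to 692.6 ± 24.9 CPM, adjusted p = 5.18e-29). IZH4, a membrane protein of zinc balance (3.66 ± 0.39), RRN3, the initiation factor of RNA polymerase I (3.40 ± 0.34), and HRP1, a factor of mRNA 3′ end formation (3.26 ± 0.17), rose on both scales. Yap1 targets rose in 11 of 27 cases and fell in 4 (median 0.31, adjusted p = 0.164 with an estimated correlation), with AAD6 (2.09 ± 0.12, and −0.23 scaled by total reads), ATR1 (1.92 ± 0.14, and −0.39) and FLR1 (1.74 ± 0.12, and −0.57). Ribosome assembly genes rose in 28 of 66 cases and fell in 2 (median 0.47), with NOG1 (1.37 ± 0.15, and −0.94 scaled by total reads) and UTP9 (1.70 ± 0.27, and −0.62). Genes for polyadenylation, decay and export rose in 7 of 19 cases and fell in 1 (median 0.52), with NRD1 (1.35 ± 0.25, and −0.97 scaled by total reads). These 2 lists had adjusted p = 0.164 with an estimated correlation. Core histone genes rose in 6 of 10 cases and fell in 1 (median 0.40), with HHF1 (2.03 ± 0.13, and −0.30 scaled by total reads). Their list had adjusted p = 0.195 with an estimated correlation. RTS3 (−2.84 ± 0.29) and the uncharacterised YGR016W (−3.55 ± 0.66) fell most beside AGA1 among genes that meet the naming rule. Outside it, MST28 had no converted read with LMB and fell at least 6.36-fold against the floor of 3 counts, so it cannot be ranked.

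In converted reads 840 of 5394 genes rose and 839 fell, and scaled by total reads 10 rose and 5220 fell. Adjusted over the list alone, 25 Hsf1 targets, 28 Gcn4 targets and 46 ribosomal protein genes fell, 30 ribosome assembly genes and 3 mating genes rose, 12 Yap1 targets rose and 5 fell, and 8 polyadenylation genes rose and 3 fell. All other counts of the lists past camera were the same. Across genes, total and nascent changes had Pearson r = 0.725 and Spearman rho = 0.715 over 5394 genes, which are not independent replicates. Background reads follow total RNA, and with 0.810% of reads taken out of each gene's converted reads r was 0.684 and 1669 of the 1679 called genes had the same sign. Of the genes called in both, 653 rose in both, 680 fell in both and 49 went opposite ways. Within single genes, the converted share of reads fell for 5343 of 5392 genes and rose for 1. It fell from 36.5% ± 1.91 to 3.46% ± 0.326 for TRX2 (thioredoxin), from 41.8% ± 0.975 to 3.86% ± 0.445 for YNL134C and from 58.5% ± 1.56 to 6.75% ± 0.720 for YLR460C. RPL6A, a protein of the large subunit, had 8.27% ± 0.526 against 6.68% ± 0.881 (log2 odds ratio 0.34 ± 0.16, adjusted p = 0.0407). That call was lost with a quasi-binomial model (0.32, adjusted p = 0.124), without LMB replicate 1 (adjusted p = 0.0614), 2 (0.0526) or 3 (0.0861) and without ethanol replicate 2 (0.250).

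The second comparison asks what changes after 16 h of 3-IAA in the Nup2-AID strain. AAD6 (YFL056C, chromosome VI, 13980 to 14805), a putative aryl-alcohol dehydrogenase, rose 70.6-fold, from 10.8 ± 2.63 to 752.4 ± 138 CPM (log2 6.14 ± 0.36, n = 3 and 3, edgeR adjusted p = 0.000541). The transporter FLR1 rose 17.2-fold (4.10 ± 0.32, from 15.9 ± 1.28 to 274.1 ± 76.3 CPM, adjusted p = 0.00235) and ECM4, a glutathione transferase, rose by 2.59 ± 0.26 on the log2 scale. Of 28 Yap1 targets 15 rose and 2 fell (median 1.67, camera adjusted p = 3.73e-09), with adjusted p = 0.0559 with an estimated correlation. OSI1 (YKL071W, chromosome XI, 305384 to 306209), an oxidative stress gene, rose from 2.06 ± 0.938 to 2255 ± 1850 CPM, and THI4 of thiamine synthesis rose from 3.27 ± 1.35 to 76.4 ± 42.9 CPM. HSP30 (plasma membrane stress protein) fell 64.7-fold, from 921.2 ± 188 to 14.1 ± 2.97 CPM (−6.02 ± 0.36, adjusted p = 0.000541), and CDC14, the phosphatase of mitotic exit, fell 52.0-fold (−5.70 ± 0.51, adjusted p = 0.00306). The transcription factor gene COM2 fell by 4.80 ± 0.60.

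Some chaperone, histone and glycolytic genes were among those that fell with 3-IAA in Nup2-AID. SSA1 (Hsp70, −4.60 ± 0.67), SIS1 (−4.08 ± 0.45) and HSP42 (−3.79 ± 0.36, from 1567 ± 395 to 113.4 ± 20.2 CPM) fell. Of 27 Hsf1 targets 12 fell and 1 rose (median −1.46, camera adjusted p = 4.53e-09), with adjusted p = 0.665 with an estimated correlation. Of 10 core histone genes 5 fell (median −1.32), with HTB1 (−5.01 ± 0.67) and HTB2 (−1.95 ± 0.26), and adjusted p = 0.478 with an estimated correlation. In glycolysis 5 of 21 genes fell and 1 rose (median −0.88), with PGK1 (−3.55 ± 0.59), TPI1 (−3.42 ± 0.55) and CDC19 (−2.52 ± 0.46). Gcn4 targets fell in 11 of 53 cases and rose in 5 (median −0.46), with ARG5,6 (−3.12 ± 0.32) and HIS5 (−2.70 ± 0.42). General stress genes fell in 6 of 31 cases and rose in 2 (median −0.50), and GLK1 fell (−2.25 ± 0.30) while HSP12 rose (3.88 ± 0.60). These lists had adjusted p = 0.665 with an estimated correlation. Methionine genes rose in 7 of 24 cases (median 0.63), as MET17 did (2.41 ± 0.36), and genes of the iron regulon rose in 5 of 21 (median 0.85), as TIS11 did (2.42 ± 0.40). Both of these had adjusted p = 0.665 with an estimated correlation. Genes within 20 kb of a chromosome end rose in 31 of 142 cases and fell in 9 (median 0.49, adjusted p = 0.478 with an estimated correlation), with the maltose activator gene MAL33 (1.77 ± 0.24). Ribosomal protein genes fell in 5 of 131 cases (median −0.64), with RPL33B (−3.57 ± 0.74), and adjusted p was 0.826 with an estimated correlation.

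In total reads 450 of 5906 genes rose and 390 fell with 3-IAA in Nup2-AID, 404 and 377 of them by over 2-fold, and 10 of the 28 lists passed camera. Adjusted over the list alone, 18 Yap1 targets rose, 37 chromosome end genes rose and 13 fell, 9 methionine genes rose and 1 fell, 10 iron genes rose and 1 fell, 16 Hsf1 targets fell and 2 rose, 9 glycolytic genes, 15 Gcn4 targets and 9 stress genes fell, and no ribosomal protein gene was called, against 5 over all genes. Markers of culture state and cell type moved in the same libraries, with the 8 post-diauxic genes at 1323 to 4154 CPM with 3-IAA and 210 to 232 CPM with ethanol, and alpha-cell genes at 1636 ± 406 and 4741 ± 929 CPM. NUP2 itself, whose reads in this strain were 2.46 to 19.04 CPM, had a log2 change of 0.20 ± 0.79 (adjusted p = 0.881), with −1.29 without 3-IAA replicate 3 and −0.02 without ethanol replicate 1. LEU2 had 0.20 ± 0.38 (adjusted p = 0.747), with −0.11 without 3-IAA replicate 1 and −0.03 without ethanol replicate 1. NUP1 (1.43 ± 0.50) was not called by edgeR (adjusted p = 0.0924) and was called by DESeq2 (1.43, adjusted p = 0.0373). CRM1 (−0.54 ± 0.34, edgeR adjusted p = 0.301) and URA3 (−0.26 ± 0.45, 0.712) were called by neither. For NUP1, 3-IAA replicate 1 read 437.5 CPM and replicates 2 and 3 read 150.8 and 141.4 CPM. The ethanol libraries read 48.7 to 98.9 CPM. Replicate 1 with 3-IAA stood apart from replicates 2 and 3 in OSI1 (141 against 3303 and 3849 CPM) and post-diauxic genes (4154 against 1323 and 1682 CPM) too. The count and the balance of rises and falls changed with the libraries used. The edgeR test called 78 genes (22 rose, 56 fell) without ethanol replicate 1, 116 (30 and 86) without ethanol replicate 2, 139 (39 and 100) without ethanol replicate 3, 551 (299 and 252) without 3-IAA replicate 3 and 1198 (515 and 683) without 3-IAA replicate 2. With a replicate block it called 282 (112 and 170), and 68 of the 840 genes were called with every library left out in turn. Without ethanol replicate 1 adjusted p was 0.0571 for OSI1, 0.0562 for TPI1, 0.0587 for CDC19, 0.0597 for HIS5, 0.0616 for HSP12, 0.0616 for MET17, 0.0651 for TIS11 and 0.0899 for RPL33B. It was 0.0524, 0.0572, 0.0638 and 0.0593 for HSP12, MET17, TIS11 and RPL33B without ethanol replicate 2, with 0.0522 for MAL33. Without ethanol replicate 3 it was 0.0501, 0.0501, 0.0612 and 0.0569 for the same genes, and for RPL33B it was 0.0668 without 3-IAA replicate 3. With adjacent library numbers as a block, a fit that left out 3-IAA replicate 1 and ethanol replicate 3, it was 0.0882 for TIS11.

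Among converted reads in Nup2-AID, scaling by total reads puts the median gene at a log2 change of −4.28, and the values that follow are scaled by TMM factors within converted reads. Background taken at the least labelled 5% of the 500 most counted genes is 26.6% to 36.1% of converted reads with 3-IAA and 30.4% to 32.6% with ethanol. Taken at 0.810% of reads it is 68.1%, 33.4% and 32.4% in 3-IAA replicates 1, 2 and 3 and 1.84% to 2.64% with ethanol, so the 3-IAA values can hold much unlabelled RNA. Chaperone RNA fell: SSA2 (Hsp70, −4.55 ± 0.54), HSP42 (−4.25 ± 0.50) and HSP104 (disaggregase, −4.07 ± 0.42, from 2048 ± 653 to 126.0 ± 27.7 CPM, n = 3 and 3, adjusted p = 0.000396). Of 27 Hsf1 targets 19 fell and 1 rose (median −1.98, camera adjusted p = 5.31e-19), with adjusted p = 0.292 with an estimated correlation. Histone genes fell in 5 of 10 cases (median −1.03, adjusted p = 0.292 with an estimated correlation), with HTB1 (−3.58 ± 0.46). Glycolytic genes fell in 9 of 21 cases and rose in 1 (median −0.84), with TPI1 (−3.18 ± 0.42) and PGK1 (−3.09 ± 0.46), and stress genes fell in 4 of 31 and rose in 1 (median −0.94), where HSP12 rose (2.04 ± 0.44, and −2.41 scaled by total reads). Both lists had adjusted p = 0.423 with an estimated correlation. Gcn4 targets fell in 11 of 51 cases and rose in 2 (median −0.56, adjusted p = 0.180 with an estimated correlation), with HOM3 (−4.10 ± 0.53) and ARG5,6 (−3.53 ± 0.39). Respiratory genes fell in 12 of 49 cases and rose in 2 (median −0.48, adjusted p = 0.666 with an estimated correlation), with COX7 falling (−2.09 ± 0.38) and CYC1, the gene of cytochrome c, rising (4.64 ± 0.47, and 0.45 with adjusted p = 0.467 scaled by total reads). Ribosome assembly genes fell in 6 of 67 cases and rose in 1 (median −0.35, adjusted p = 0.236 with an estimated correlation), with RRP12 (−2.27 ± 0.40), and adenine genes fell in 1 of 14 (median −0.61, adjusted p = 0.438 with an estimated correlation).

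The converted reads that rose with 3-IAA in Nup2-AID included OSI1 (8.55 ± 0.77), AAD6 (6.61 ± 0.39, from 18.99 ± 5.07 to 1835 ± 214 CPM, adjusted p = 5.33e-06) and SNO4, a heat shock chaperone near a chromosome end (5.56 ± 0.45). Yap1 targets rose in 8 of 26 cases and fell in 1 (median 0.62, adjusted p = 0.182 with an estimated correlation), with FLR1 (2.41 ± 0.35, and −1.87 scaled by total reads). Chromosome end genes rose in 17 of 94 cases and fell in 3 (median 0.48, adjusted p = 0.180 with an estimated correlation). Iron genes rose in 3 of 19 cases (median 0.87, adjusted p = 0.575 with an estimated correlation), with the reductase gene FRE3 (3.11 ± 0.59, and −1.24 scaled by total reads), whose call was lost with adjacent library numbers as a block (2.34, adjusted p = 0.126). In all 321 of 5370 genes rose and 323 fell, and 4 rose and 5331 fell scaled by total reads. Adjusted over the list alone, 23 Hsf1 targets, 10 glycolytic genes, 12 stress genes and 4 adenine genes fell, 15 Gcn4 targets fell and 5 rose, 14 respiratory genes fell and 3 rose, 9 ribosome assembly genes fell and 2 rose, 9 Yap1 targets rose, 19 chromosome end genes rose and 5 fell, and 5 iron genes rose and 1 fell. For 11 genes with no converted read in the 3-IAA libraries the change is a lower bound, from at least 1.98-fold to at least 8.28-fold lower against a floor of 3 counts over the group. Without ethanol replicate 1 the count was 278 (138 rose, 140 fell), without ethanol replicate 2 it was 211 (75 and 136), without ethanol replicate 3 it was 217 (85 and 132) and without 3-IAA replicate 2 it was 365 (179 and 186), while a replicate block gave 299 (111 and 188). HSP12 lost its call without 3-IAA replicate 1 (adjusted p = 0.0645) or 3 (0.0530) and without ethanol replicate 2 (0.0557) or 3 (0.0644), and with adjacent library numbers as a block (0.0595). That last fit, also given for FRE3 above, left out 3-IAA replicate 1 and ethanol replicate 3.

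Across genes, total and nascent changes in Nup2-AID had Pearson r = 0.735 and Spearman rho = 0.749 over 5368 genes. From mean log2 CPM r was 0.71, and with 0.810% of reads taken out of each gene's converted reads as background it was 0.413, with 606 of 642 called genes at the same sign. Of the genes called in both, 171 rose in both and 178 fell in both. Within single genes the converted share fell for 5349 of 5360 genes. It fell from 39.4% ± 11.7 to 0.524% ± 0.237 for AHP1 (peroxiredoxin), from 92.6% ± 4.35 to 0.565% ± 0.979 for ADH2 (the glucose-repressed alcohol dehydrogenase) and from 35.9% ± 7.19 to 0.593% ± 0.160 for YNL134C (n = 3 and 3, edgeR adjusted p = 1.73e-46, 1.85e-37 and 4.67e-39).

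**Figure D3:**
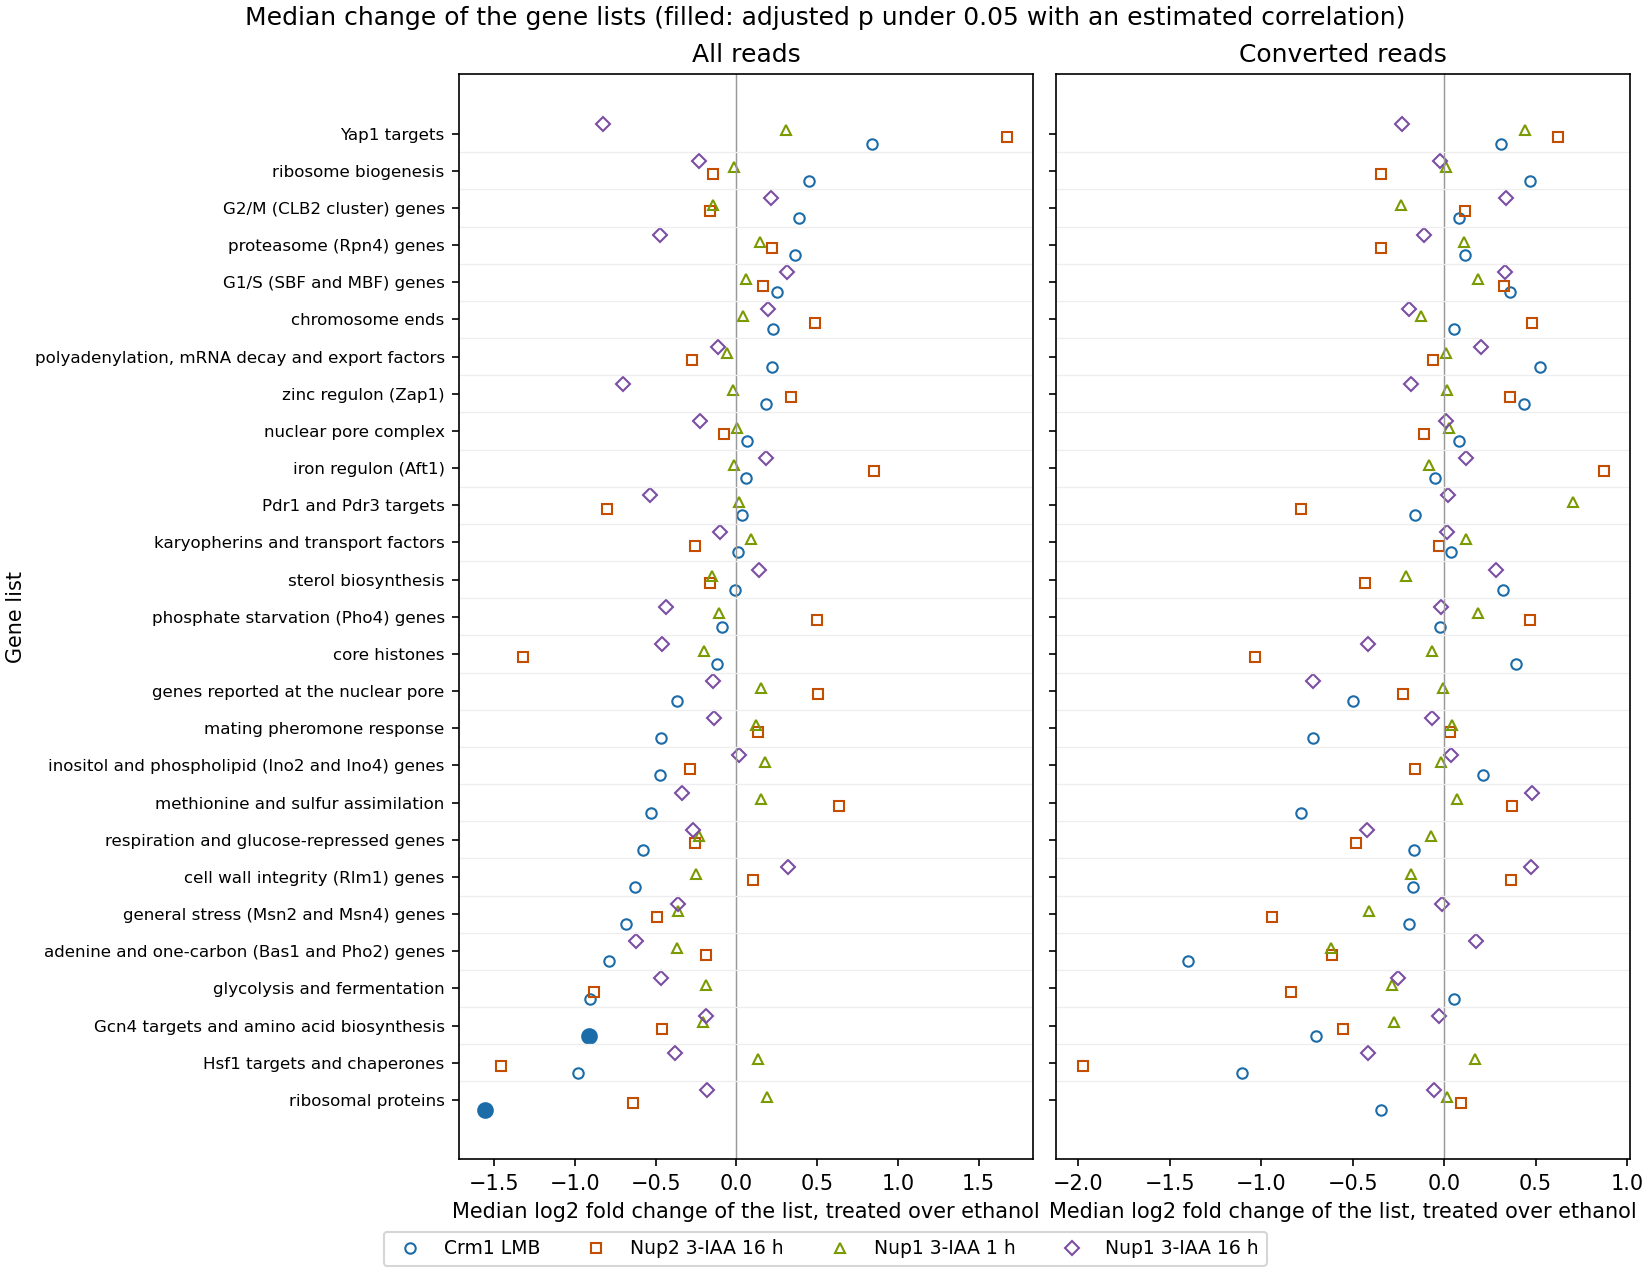
Median log2 fold change (treated over ethanol) of each gene list in all reads and in converted reads, with 1 symbol per comparison. Filled symbols mark adjusted p under 0.05 with an estimated correlation, which only Gcn4 targets (median −0.91) and ribosomal proteins (median −1.56) reach, both after LMB in all reads.

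The third comparison asks what 1 h of 3-IAA does in the Nup1-AID strain. No gene was called in total reads among 6220 tested (edgeR quasi-likelihood test), with 108 at an unadjusted p under 0.05 and none by DESeq2, which had 165 at an unadjusted p under 0.05. NRE1, the gene of a putative dehydrogenase (log2 −0.87 ± 0.22), PRY2, a sterol-binding protein gene (−1.0 ± 0.26), and YKL153W (−4.85 ± 1.43) had the smallest p-values (n = 7 and 7, edgeR adjusted p = 1.00). With replicates 2 to 5 alone and replicate number as a block, a subset chosen after seeing the data, 73 genes were called, PRY2 (adjusted p = 0.00613) and NRE1 (0.0247) among them. Adenine genes had a median of −0.37 (camera adjusted p = 4.04e-07, and adjusted p = 0.136 with an estimated correlation), with SHM2 (−1.28 ± 0.39) and ADE6 (−0.99 ± 0.35), and 1 of 14 fell adjusted over the list alone. Hsf1 targets (0.14), Yap1 targets (0.31), stress genes (−0.36), respiratory genes (−0.23) and methionine genes (0.15) passed camera with these medians, and each had adjusted p = 0.738 with an estimated correlation. Their members were not called, over all genes or adjusted over the list alone. Libraries of the same replicate number correlated at 1 h (0.307 to 0.788), but replicates 3, 6 and 7 matched another number better. Replicate 7 had 0.307 with its own number and up to 0.742 with another, so pairing is not established. Paired by number, the mean of the Yap1 targets was higher with 3-IAA in 6 of 7 pairs and the same to 2 decimals in 1. With replicate number as a block 13 lists passed camera, Yap1 targets among them with a median of 0.49, and none did with an estimated correlation (adjusted p = 0.323 for Yap1 targets).

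In converted reads at 1 h no gene of 3657 was called by edgeR, with 115 at an unadjusted p under 0.05 and none by DESeq2. In a self-test this test recovered 0 of 95 planted 2-fold and 40 of 95 planted 4-fold changes. With replicate number as a block, in a fit of the 2 groups, edgeR called 1 gene of 1275, OSI1 of oxidative stress (1.91 ± 0.37, adjusted p = 0.0238), with 44 at an unadjusted p under 0.05. That call was lost without both libraries of replicate 6 (1.70 ± 0.40, adjusted p = 0.181) and held without those of any other number. Without a block ADR1, the activator of glucose-repressed genes (2.47 ± 0.73), COX20, an assembly factor of cytochrome oxidase (−2.41 ± 0.74), and the glucose transporter gene HXT1 (1.58 ± 0.49) had the smallest p-values (n = 7 and 7, edgeR adjusted p = 0.998). The lists past camera were Yap1 targets (median 0.44), Pdr1 and Pdr3 targets of drug resistance (0.70) and adenine genes (−0.62). Their adjusted p-values with an estimated correlation were 0.947, 0.464 and 0.485, and with a replicate block they were 0.110, 0.110 and 0.612. No converted share was called among 1275 genes, with none at an unadjusted p under 0.05, in a test that recovered 0 of 100 planted 2-fold and 0 of 100 planted 4-fold changes and so cannot show that shares stayed the same. SLD3 (−1.45), RPB4 (2.57) and SPT20 (1.13) had the smallest p-values (log2 odds ratios, edgeR adjusted p = 1.00).

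After 16 h of 3-IAA in the Nup1-AID strain, 1 gene was called in total reads among 6220. PHO5 (YBR093C, chromosome II, 429223 to 430048), which codes for the secreted acid phosphatase, rose 6.18-fold, from 11.0 ± 3.68 CPM (n = 5) to 68.0 ± 22.8 CPM (n = 4, log2 2.63 ± 0.42, edgeR adjusted p = 0.0128). PHO5 also read 51.8 to 79.0 CPM in the Nup2-AID libraries with 3-IAA and 6.44 to 10.2 CPM in their controls. Its call was lost without ethanol replicate 1 (adjusted p = 0.0839), 2 (0.0842) or 3 (0.0648) and without 3-IAA replicate 1 (0.0542) or 3 (0.0513), and also with only the 2 groups in the fit (0.178), with a replicate block (0.982) and with adjacent library numbers as a block (0.898). Its log2 change stayed between 2.44 and 2.83 with any library left out, and was 2.60, 2.70 and 2.52 in those 3 fits. Both block fits also held only the 2 groups. They left out ethanol replicate 5 (replicate block) or 1 (adjacent numbers), so they do not test the block alone. Single libraries read 41.7 to 98.5 CPM for PHO5 with 3-IAA and 6.57 to 15.3 CPM with ethanol. Without 3-IAA replicate 4 the test called 46 genes. There were 534 genes at an unadjusted p under 0.05, and DESeq2 called 45. POM152, of the pore's membrane ring, was not called by edgeR on all libraries (−1.17 ± 0.32, adjusted p = 0.235) but was called by DESeq2 (−1.18, adjusted p = 0.0485) and by edgeR without 3-IAA replicate 4 (−1.60, 0.0273). NSP1, of the central channel, was called by neither tool (−0.99 ± 0.37, edgeR adjusted p = 0.437). The list of 33 pore complex genes had a median of −0.22 (camera adjusted p = 0.00644), and adjusted p = 0.359 with an estimated correlation, with 1 gene falling adjusted over the list alone.

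Other lists past camera at 16 h in Nup1-AID lost their call with an estimated correlation. Cell wall genes had a median of 0.32 (adjusted p = 0.359 with an estimated correlation), and ribosome assembly genes (−0.23) and proteasome genes (−0.48), with RPN3 (−1.70 ± 0.65) and PRE4 (−1.15 ± 0.48), had adjusted p = 0.649 with it. Hsf1 targets (−0.38), among them SSA4 (−2.42 ± 0.87), and genes of glycolysis (−0.47), respiration (−0.27), the zinc regulon (−0.70), chromosome ends (0.19), adenine synthesis (−0.63) and histones (−0.46) had adjusted p = 0.626 with an estimated correlation, and G1/S genes (0.32) had 0.635. Of these 1 respiratory gene rose adjusted over the list alone. Of the 15 phosphate starvation genes PHO5 rose, and 1 other fell adjusted over the list alone. In converted reads no gene of 3657 was called by edgeR, with 166 at an unadjusted p under 0.05 and none by DESeq2, and SAG1, the agglutinin of alpha cells (−3.12 ± 0.84), HRT1 (−3.73 ± 1.12) and VPS53 (−3.57 ± 1.08) had adjusted p = 0.870. Hsf1 targets had a nascent median of −0.42 (camera adjusted p = 0.0345, and 0.882 with an estimated correlation). No converted share was called among 5324 genes, with none at an unadjusted p under 0.05, and YHR180W-A (−6.27), MAE1 (−5.80) and YLR255C (−5.16) had the smallest p-values (log2 odds ratios, edgeR adjusted p = 1.00). Neither of these tests at 16 h recovered a planted 2-fold or 4-fold change (0 of 95 and 0 of 93 in converted reads, 0 of 100 and 0 of 100 in converted shares), so they leave such changes open.

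Libraries with under 1% converted reads stood apart in gene expression as well, in both treatments of Nup1-AID. This division of the libraries, and TRX2 and OSI1 as measures, were chosen after seeing the data. TRX2 ranged from 23600 to 37740 CPM in them and from 408 to 7699 CPM in the other libraries of the series. OSI1 read 3656 to 8574 CPM in them. It read 6377 and 9349 CPM in Nup1-AID 3-IAA replicates 1 and 2 at 16 h, which held 1.64% and 2.69% converted reads. The remaining Nup1-AID libraries read 6.78 to 336 CPM, so within this strain OSI1 was high where label was low. In Nup2-AID with 3-IAA it read 141 to 3849 CPM. Across the libraries under 1%, 8 genes of the post-diauxic phase summed to 6303 to 11390 CPM against 210 to 4154 CPM elsewhere. The mean log2 CPM of Yap1 targets ranged over 4.24 within the 1 h ethanol group and over 3.19 within the 16 h ethanol group, while it ranged over 0.12 and 0.47 within the Nup2-AID ethanol and 3-IAA groups, whose means differ by 1.43. NUP1 reads in this strain were 0 to 19.3 CPM, and 48.7 to 437.5 CPM in Nup2-AID. They were as low with ethanol (at most 10.95 CPM at 1 h and 16.7 CPM at 16 h). The degron acts on protein, so these reads do not show whether Nup1 was lost. Loss of Nup1 or Nup2 protein was not measured here.

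**Figure D4:**
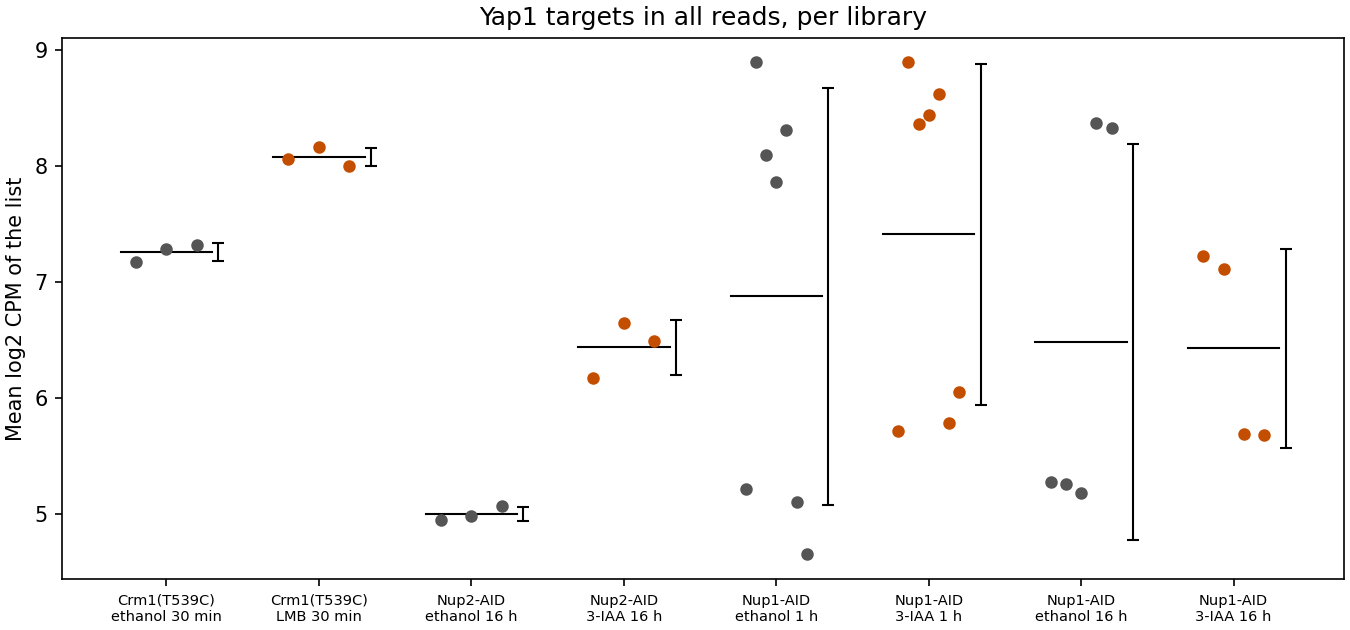
Mean log2 CPM of the Yap1 target list in all reads, with 1 point per library, horizontal lines at group means and bars of 1 SD. Values lie between 4.65 and 8.89 in the 1 h ethanol group of Nup1-AID, and between 4.95 and 5.07 in the ethanol group of Nup2-AID.

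Tests of the difference ask whether 3-IAA acted differently between the Nup1-AID times and between Nup1-AID and Nup2-AID at 16 h. Between 16 h and 1 h no gene was called by edgeR in total reads, with 449 at an unadjusted p under 0.05 and 6 by DESeq2, or in converted reads, with 171 and none. PHO5 (2.51 ± 0.53), SAG1 (−2.05 ± 0.43) and BAT2, of branched-chain amino acid breakdown (1.96 ± 0.45), had the smallest p-values in total reads (adjusted p = 0.259, 0.259 and 0.412), which DESeq2 put at 0.0132, 0.0163 and 0.0475. ZAP1 (−5.99), SAG1 (−3.53) and TRX1 (−3.55) did in converted reads (adjusted p = 0.998). In total reads 11 lists passed camera. Hsf1 targets (median difference −0.59), cell wall genes (0.64) and pore complex genes (−0.19) had adjusted p = 0.364 with an estimated correlation. Proteasome (−0.51), ribosome assembly (−0.22), G2/M (0.54), Yap1 (−1.05), methionine (−0.63), Pdr1 and Pdr3 (−0.53), karyopherin (−0.16) and zinc genes (−0.60) had 0.802. Fewer lists passed without the Nup1-AID libraries under 1% converted. The Yap1 value rests in part on 2 of these, 16 h ethanol replicates 4 and 5 (list means of 8.37 and 8.32). Ethanol replicates 1 to 3 lay at 5.18 to 5.27 and the 3-IAA libraries at 5.68 to 7.22. In converted reads Hsf1 targets passed (−0.64, and adjusted p = 0.768 with an estimated correlation).

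Between Nup1-AID and Nup2-AID no gene was called by edgeR in total reads, with 526 at an unadjusted p under 0.05 and 24 by DESeq2, or in converted reads, with 367 and 2. HSP42 (2.96 ± 0.59) and SIS1 (3.05 ± 0.60) had adjusted p = 0.442 and HAP4, the activator of respiration genes (2.16 ± 0.48), 0.524, which DESeq2 put at 0.00121, 0.00121 and 0.0134. In converted reads HSP30 (4.01 ± 0.85), RNR3 (−6.93 ± 1.41) and ARG80 (−6.47 ± 1.44) had adjusted p = 0.247, and DESeq2 put HSP30 at 0.0397. Hsf1 targets differed by a median of 1.20 in total reads (camera adjusted p = 3.23e-10, and 0.358 with an estimated correlation), with 8 higher and 1 lower adjusted over the list alone, and by 1.57 in converted reads (2.78e-13, and 0.275), with 12 higher. Also past camera in total reads were Yap1 targets (−2.26), ribosomal proteins (0.58), methionine (−1.25), proteasome (−0.75), phosphate (−1.17), glycolysis (0.43), Gcn4 (0.44), histone (0.96) and G1/S genes (0.51), each with adjusted p = 0.704 with an estimated correlation. Much of the −2.26 comes from Nup1-AID ethanol replicates 4 and 5, with Yap1 list means of 8.37 and 8.32. In that strain ethanol replicates 1 to 3 lay at 5.18 to 5.27 and 3-IAA libraries at 5.68 to 7.22. In converted reads they were glycolysis (0.65), Yap1 (−0.69), Gcn4 (0.53), chromosome end (−0.32), adenine (0.72) and iron genes (−0.62). Adjusted p-values for these with an estimated correlation were 0.367, 0.658, 0.505, 0.275, 0.481 and 0.367, and 1 Yap1 target and 1 chromosome end gene were lower adjusted over the list alone.

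Genes that changed after LMB and in Nup2-AID were compared to ask what the treatments share. In total reads 187 genes fell in both, against 112 expected from the counts (Fisher's exact test, two-sided, p = 9.31e-17, adjusted p = 2.79e-16), 147 rose in both, against 124 expected (p = 0.0156, adjusted p = 0.0234), and 139 went opposite ways. The excess of shared rises in total reads rests on the ethanol libraries of Nup2-AID: without replicate 1, 2 or 3 of these, 5, 9 or 11 genes rose in both, against 6.14, 8.37 and 10.9 expected (unadjusted p = 0.812, 0.839 and 1.00). It was also lost without 3-IAA replicate 1 (190 against 172 expected, Fisher's exact test, unadjusted p = 0.0969) and with a replicate block in Nup2-AID (35 against 31.1, p = 0.396), while it was 99 against 82.8 expected without 3-IAA replicate 3 (p = 0.0336) and larger without 3-IAA replicate 2 (199 against 143, p = 2.25e-08). Shared falls numbered 39, 54 and 63 without ethanol replicates 1, 2 and 3 (15.3, 23.9 and 27.9 expected, Fisher's exact test, unadjusted p = 1.65e-11, 6.04e-12 and 1.01e-13), 110 without 3-IAA replicate 3 (71.4 expected), 333 without 3-IAA replicate 2 (195 expected) and 90 with a replicate block (48.4 expected). In converted reads 126 fell in both, against 50.6 expected (adjusted p = 2.51e-25), 81 rose in both, against 44 expected (adjusted p = 1.89e-08), and 41 went opposite ways. Without ethanol replicates 1, 2 and 3 or 3-IAA replicate 2 of Nup2-AID, 65, 74, 68 and 79 fell in both (24.8, 24.0, 23.2 and 28.9 expected) and 35, 22, 24 and 51 rose in both (22.3, 11.8, 13.5 and 25.7 expected, unadjusted p = 0.00443, 0.00324, 0.00372 and 5.26e-07). Both treated groups had lost most label, with 4.66% and 2.04% converted reads. The overlap in converted reads can therefore also come from that loss and from background, and it was not computed with background taken out. HSP42 and RPL33B fell and FLR1 rose in the total reads of both, and HSP42 fell and AAD6 and FLR1 rose in the converted reads of both. Over all genes r was 0.222 in total reads (rho = 0.196) and 0.286 in converted reads. Genes are not independent replicates, for r or for the Fisher tests above, whose p-values may thus be too small. Between Nup2-AID and Nup1-AID at 16 h r was 0.288 in total reads (rho = 0.305) and 0.188 in converted reads. For the other pairs in total reads r was 0.007 (LMB and Nup1-AID at 1 h), −0.024 (LMB and Nup1-AID at 16 h), −0.019 (Nup2-AID and Nup1-AID at 1 h) and −0.051 (Nup1-AID at 1 h and 16 h). In all 12 pairs were computed, and 6 overlap tests had genes called on both sides.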

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

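Splits of the libraries into other groups, the ribosomal protein tests and the tests of labelling and of Yap1 targets below were run after the results were seen, except that the ribosomal protein tests were written down before they were run.

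The share of converted reads fell in nearly every gene, 99.1% of those tested after LMB and 99.8% in Nup2-AID with 3-IAA, so a changed mix of genes in the libraries is argued against. Fewer new transcripts with unchanged label in each would leave conversions per converted read as they were, but after taking out background they were at most 1.40 with LMB against at least 1.75 in its controls, and at most 1.10 against at least 1.84 in Nup2-AID. With background set at 0.810% of reads instead they were at most 1.30 against at least 1.67, and at most 1.12 against at least 1.60. For LMB this argues against that explanation only as far as background was no larger than taken out. For Nup2-AID the test cannot decide. Before background was taken out, converted reads there held 1.04 to 1.07 conversions with 3-IAA. Nup1-AID libraries with hardly any label held 1.08 to 1.22, so most converted reads in Nup2-AID with 3-IAA may be background. Less label built into each new transcript, or less of it read as a conversion, may explain the pattern, since converted reads held at most 1.25 conversions with LMB (1.64 to 1.66 in controls) and at most 1.07 in Nup2-AID with 3-IAA (1.59 to 1.72). With LMB 4.29% to 5.16% of reads were converted, against at most 0.810% in the Nup1-AID libraries with hardly any label. If background was alike in these batches, that argues against a wholly missed pulse with LMB. No value here separates uptake of 4-thiouracil, its turnover into a nucleotide and alkylation, or in Nup2-AID a missed pulse. The step at which label was lost therefore stays open.

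Lower ribosomal protein reads after LMB could come from windows away from the gene end or from reads shared between near-identical copies. Without misplaced windows the list median was −1.94 and among 18 single-copy genes it was −1.97, against −1.56 for the list as a whole, which argues against both. No biological explanation was tested. In converted reads, scaled by TMM factors within them, the median was −0.41 in the 85 genes with a window at the gene end, of which 39 fell and 7 rose.

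Higher Yap1 target reads in Nup2-AID with 3-IAA could come from Nup2 or from the state of the cultures, and these cannot be told apart. The list mean ranged over at most 0.47 log2 units within a Nup2-AID group, less than the 1.43 between them, yet post-diauxic genes differed between the same groups (1323 to 4154 against 210 to 232 CPM). 3-IAA itself also stays open, since the list median in Nup1-AID was 0.31 at 1 h and −0.83 at 16 h. That −0.83 rests on ethanol replicates 4 and 5 (list means of 8.37 and 8.32), while the 3-IAA libraries lie at 5.68 to 7.22 and ethanol replicates 1 to 3 at 5.18 to 5.27. In Nup1-AID at 1 h the list mean was 7.86 to 8.89 in replicates 2 to 5 (under 1% converted) and 4.65 to 6.05 in the others. At 16 h it was 7.22 and 7.11 in 3-IAA replicates 1 and 2 (1.64% and 2.69% converted). Replicates 3 and 4 (30.3% and 26.8%) had 5.69 and 5.68. LMB and Nup2-AID with 3-IAA likewise had less label and a higher list mean than their controls. The rise and the loss of label thus go together, and which depends on which was not tested.

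With 3 against 3 libraries there are only 10 splits, too few to judge by. For LMB the real groups called 3487 genes in total reads, 1679 in converted reads and 5344 converted shares, where the highest other split called 0 each time, so 1 of 10 splits reached the real count. Lists called were 15 (1 of 10 splits, highest other 12) and 12 (1 of 10 splits, highest other 7). For Nup2-AID the real counts were 840, 644 and 5349 with 0 in the highest other split, 1 of 10 splits each. Lists called there were 10 (4 of 10 splits, highest other 13) and 11 (1 of 10 splits, highest other 9).

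In Nup1-AID most other splits called 0 genes, as the real groups did, and a few called many, which points to structure among the samples in those splits. Where the real count is 0 all 100 of 100 splits reach it by construction, so those tallies say nothing about chance. At 1 h the real 0 genes stand beside 4 other splits that called any in total reads (highest 1800), 8 in converted reads (highest 377) and 16 in converted shares (highest 1272). At 16 h they were 8 in converted reads (highest 22) and 5 in converted shares (highest 5305). Between the Nup1-AID times no other split called a gene in total reads (highest 0) and 12 did in converted reads (highest 13), and between the AID strains 3 and 9 did (highest 898 and 151).

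Libraries of the same replicate number correlate at 1 h, though pairing is not established. The real groups were therefore also compared with the splits that part all 7 pairs, using a replicate block, where the others swap treatment within some pairs. In converted reads 1 of 64 such splits reached the real 1 gene (highest other 0), which taken alone argues against chance for that count. It is 1 of many such tallies, unadjusted for their number, and the count was 0 without both libraries of replicate 6. Chance is therefore not excluded for it. In total reads the real 0 genes were reached in 64 of 64 by construction (highest other 1).

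Chance cannot be excluded for the other Nup1-AID counts either. The real 1 gene in total reads at 16 h was reached in 8 of 100 splits (highest 683). Lists at 1 h reached 7 in 64 splits (highest 18) and 3 in 50 splits (highest 12), and at 16 h they reached 12 in 15 splits (highest 15) and 1 in 85 splits (highest 12). Between the times lists reached 11 in 33 splits (highest 20) and 1 in 91 splits (highest 12), and between the strains 10 in 38 splits (highest 18) and 7 in 26 splits (highest 12). Among the 8 splits that part every pair of 1 h replicates 2 to 5, too few to judge by, the real grouping called 73 genes and the highest other 0.

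Nup1-AID 3-IAA replicate 3 at 1 h had 2.63 M reads, the nearest library of its group 7.32 M (Dixon ratio 0.639). Nup1-AID ethanol replicate 1 at 16 h had 2.32 conversions per converted read, the nearest 1.37 (ratio 0.793). Of 40 such tests 2 marked an outlier, and chance marks about 1 in 20 groups. The change in labelled share with 3-IAA at 16 h differed between the AID strains by 35.1 percentage points, in a test that cannot part it from a difference in baseline. Strain coincides with library batch there, and ethanol replicates 4 and 5 of Nup1-AID had 0.609% and 0.387% converted reads. Lists past camera in the difference tests numbered 11 in total and 1 in converted reads between the Nup1-AID times, and 10 in total and 7 in converted reads between the AID strains.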

How the results depend on the processing

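The subsets of Nup1-AID libraries and the list tests with a replicate block in this part were chosen after seeing the results, and the other tests were planned. After LMB gene counts were 3069 to 3308 in total and 1316 to 1522 in converted reads with any library left out, and 2699 (77.4%) and 887 (52.8%) of the genes were called every time. Total-read scaling called 5230 genes in converted reads, and the converted share was called for 3362 of 3373 genes with a mean of at least 50 converted reads. Nup2-AID total reads called 840 genes, 1407 with DESeq2, 282 with a replicate block and 307 with adjacent library numbers as a block. This last fit left out 3-IAA replicate 1 and ethanol replicate 3. Leaving out 1 library gave 78 (ethanol replicate 1) to 1198 (3-IAA replicate 2), with 116 and 139 without ethanol replicates 2 and 3, 551 without 3-IAA replicate 3 and 1147 without 3-IAA replicate 1, and 68 genes (8.1%) were called every time. Nup2-AID converted reads called 644 genes, 1143 with DESeq2, 5335 with total-read scaling and 299 with a replicate block, and 211 (without ethanol replicate 2) to 571 (without 3-IAA replicate 1) with 1 library left out, 132 of them (20.5%) every time. With an estimated correlation the lists called went from 15 to 2 (LMB total), 12 to 0 (LMB nascent), 10 to 0 and 11 to 0 (Nup2-AID), 7 to 0 and 3 to 0 (Nup1-AID at 1 h), 12 to 0 and 1 to 0 (16 h), 11 to 0 and 1 to 0 (16 h against 1 h), and 10 to 0 and 7 to 0 (Nup1-AID against Nup2-AID). Total-read scaling called 5 lists in Nup2-AID nascent reads. For Nup1-AID at 1 h, replicates 2 to 5 only with a replicate block called 73 genes in total reads, and lists were 13 with a replicate block, 14 for replicates 2 to 5 and 14 for them with a block. In its nascent reads a replicate block called 1 gene, and lists were 6 for replicates 1, 6 and 7, 6 for them with a block and 1 for replicates 2 to 5 with a block. At 16 h total genes were 45 with DESeq2, 0 with a replicate block, 0 with only the 2 groups, 0 with adjacent library numbers, 2 without ethanol replicates 4 and 5, and 0 to 46 with 1 library left out (46 without 3-IAA replicate 4, 2 without ethanol replicate 5). Nascent lists at 16 h were 3 with total-read scaling, 0 with a replicate block and 9 without ethanol replicates 4 and 5. For 16 h against 1 h DESeq2 called 6 genes and leaving out 3-IAA 16 h replicate 4 called 1, and without libraries under 1% converted 2 lists were called in total and 2 in nascent reads, where total-read scaling gave 3. For Nup1-AID against Nup2-AID DESeq2 called 24 and 2 genes, and 1 nascent gene was called without Nup1-AID 3-IAA replicate 4. Leaving out 1 library put the labelled share difference between −16.06 and −14.85 points for LMB, −38.67 and −31.99 for Nup2-AID, −5.47 (without 3-IAA replicate 1) and 2.93 (without ethanol replicate 6) for Nup1-AID at 1 h, and −5.18 (without 3-IAA replicate 3) and 4.37 (without 3-IAA replicate 1) at 16 h. With a mean of at least 50 reads the across-gene correlation was 0.273 for LMB and Nup2-AID, 0.072 for LMB and Nup1-AID at 1 h, 0.005 for LMB and Nup1-AID at 16 h (−0.024 before), −0.065 for Nup2-AID and Nup1-AID at 1 h, −0.115 between the Nup1-AID times, and 0.226 in nascent reads of Nup2-AID and Nup1-AID at 16 h. Total-read scaling reversed, in nascent reads after LMB, LYS20 (−0.76), ATR1 (−0.39), AAD6 (−0.23), FLR1 (−0.57), NOG1 (−0.94), UTP9 (−0.62), HHF1 (−0.30) and NRD1 (−0.97), and in Nup2-AID FLR1 (−1.87), FRE3 (−1.24) and HSP12 (−2.41). It put the median gene at −0.19 in Nup1-AID at 1 h and at −0.11 at 16 h. In Nup2-AID total reads NUP2 was −0.24 with a replicate block and −1.29 (without 3-IAA replicate 3) to 0.58 with 1 library left out, and LEU2 was −0.11 (without 3-IAA replicate 1) to 0.47. HRT1 was 0.19 with a replicate block in nascent reads at 16 h, ZAP1 was 0.01 without libraries under 1% converted in the 16 h against 1 h nascent test, and RPB4 was −0.74 with the quasi-binomial test at 1 h. For PHO5 at 16 h adjusted p was 8.43e-07 with DESeq2, 0.982 with a replicate block, 0.178 with only the 2 groups, 0.898 with adjacent library numbers, 0.0268 without ethanol replicates 4 and 5, and 0.00786 to 0.0842 with 1 library left out.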

Other observations

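The look at FUR1 and FUR4 in this part was chosen after seeing the results, and the lists and markers were fixed before. Lists not called in total reads after LMB were mixed. Polyadenylation, decay and export genes rose in 8 of 20 cases and fell in 5 (median 0.22, camera adjusted p = 0.116), G2/M genes rose in 10 of 19 and fell in 2 (0.39, 0.193), and G1/S genes rose in 8 of 29 and fell in 4 (0.25, 0.314). Chromosome end genes rose in 57 of 169 and fell in 40 (0.23, 0.314), Pdr1 and Pdr3 targets rose in 4 of 17 and fell in 4 (0.03, 0.455), and sterol genes rose in 4 of 24 and fell in 8 (−0.01, 0.611). Histone genes rose in 2 of 10 and fell in 3 (−0.12, 0.611), and pore complex genes rose in 8 of 33 and fell in 5 (0.07, 0.637). Phosphate genes rose in 2 of 15 and fell in 4 (−0.09, 0.646), karyopherins rose in 7 of 28 and fell in 8 (0.01, 0.819), and iron genes rose in 5 of 21 and fell in 5 (0.06, with a test direction of down, 0.869). Zinc genes rose in 6 of 12 and fell in 3, with a median of 0.19 against a mean of −0.12 and a test direction of up (0.918). Adjusted over the list alone, 2 G1/S genes fell, 7 pore complex genes rose and 4 fell, 1 phosphate gene rose and 3 iron genes rose, and the other counts were the same.

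Markers of strain and cell type differed between the strains. Alpha-cell genes read 771 to 5769 CPM and a-cell genes 40.2 to 147 CPM in the AID strains. CRM1 read 14.8 to 30.8 CPM in the Crm1(T539C) strain and 37.6 to 175 CPM in the AID strains, URA3 189 to 373 against 2619 to 7438 CPM, and LEU2 11.4 to 24.2 against 27.97 to 370 CPM. LEU2, the marker in the Crm1(T539C) strain, thus read lower there than in the AID strains. FUR1, which converts uracil for nucleotide synthesis, read 115 CPM with LMB and 205 CPM in its controls, and 258 and 417 CPM in Nup2-AID with 3-IAA and ethanol. FUR4, the uracil permease, went the other way, with 37.2 and 22.3 CPM, and 86.6 and 40.9 CPM.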
